A study of Mus musculus with 2 samples.

How the data were processed

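Poly(A)-selected RNA was sequenced from the left cerebral cortex of mice aged 6 months (strain B6NCrl, a C57BL/6 substrain), with 20 ng of starting RNA and Nextera tagmentation, in which a transposase cuts and tags the cDNA, per the labels. The labels gave 1 group, cortex, with 2 libraries numbered as biological replicates 1 and 2. They carried separate biosample records and the same donor entry, so that whether the libraries came from separate animals rests on the replicate labels alone, and every spread below measures only the difference between these libraries. The labels described the tissue as male and, in another field, gave the sex as not collected.

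Each library had 3 deposited tables, all on mm10 with GENCODE M21 annotation, per the notes deposited with the tables. The gene table and the first transcript table held expected counts, TPM and, for transcripts, the percent of the gene's TPM (isoform percent), all computed by the authors from alignments to the transcriptome, per the file headers and the deposited notes. The second transcript table held estimated counts and TPM that the authors made from the pair of read files, per the deposited notes. The column layouts were those that RSEM and kallisto write; the names and versions of the aligner and quantifiers, and any use of strand, are not given in the sources used here. Expected and estimated counts were deposited without normalization, and the deposited TPM was scaled by the authors to the same sum in each library, over genes, spike-ins and, in the gene tables, rows with numeric names, as the sums of the deposited columns showed. Depth on genes was 51888490 fragments in replicate 1 and 26776276 in replicate 2 in the gene tables, and 76100574 and 46367538 in the second transcript tables. Rows with numeric names (26248), whose identity is not given in the sources used here, and spike-in rows (97) stayed out of library sizes and tests and held 1.73e-05 and 3.35e-05 percent of the gene table fragments. Of 55536 gene rows, 55450 carried a symbol and had a counterpart in the second transcript table. A list symbol found on more than 1 row (1 symbol, Rmrp) was given the row with most fragments.

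A gene counted as detected at a TPM of at least 1 in both libraries. 40 gene lists, of which 14 named cell types, 2 cortical layers, 5 other brain regions and 18 functions, with 1 list of Y-linked genes and Xist, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The level of a list was the median TPM of its genes per library, given as mean ± SD over 2 libraries. That SD is of the list medians and does not show how far the members differ between the libraries. With 2 libraries per group even a comparison of 2 groups could not go below an exact two-sided p of 0.333, so lists were set side by side by level and spread only.

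Expected counts were rounded to whole numbers and the libraries were compared gene by gene with an exact two-sided binomial test at TMM effective library sizes (edgeR 4.0.16 in R 4.3.3), adjusted by Benjamini-Hochberg over genes with a mean CPM of at least 1, at a threshold of 0.05. That test sets 1 library against 1 and compares those libraries, not conditions. Log2 ratios (replicate 2 over replicate 1) used CPM plus a pseudocount of 0.5, which pulls low genes toward 0; 95% Clopper-Pearson intervals of the ratio, without pseudocount, and the floor of 3 counts where a library held none cover counting error only, since the libraries carried no molecular identifiers. The common biological coefficient of variation came from edgeR with an intercept alone. For each list the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart outside the central 95 percent. Lists with fewer than 3 tested genes were not placed. The gene table and the summed second transcript table were compared by the log2 ratio of TPM with a pseudocount of 0.1, and a gene differed at 2-fold or more in the same direction in both libraries at a mean TPM of at least 5. The main transcript of a gene was the one with the highest TPM, at a gene TPM of at least 10 and with 2 or more annotated transcripts. GC content was taken from the annotated transcripts, weighted by their TPM, for 14646 of 14656 tested genes, and trends on GC content and length were removed with a lowess smoother at a fraction of 0.3 (statsmodels 0.14.6).

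Named genes were the 20 nuclear protein coding genes with the highest mean TPM, the 2 highest members and the lowest of each list with all Y-linked genes and Xist, the 12 genes with the largest log2 ratio in each direction at a mean CPM of at least 5, up to 4 members of each list that stood apart, the 6 genes with the largest ratio between quantifications in each direction at a mean TPM of at least 10, and the isoforms of 15 fixed genes. Some genes under this rule are not reported here.

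The test between the libraries was tested on simulated Poisson counts drawn from the real means and library sizes, with 50 genes changed at each fold. Over 14608 genes, it recovered 100% of those raised 2-fold, 86% of those lowered 2-fold, 84% of those raised 1.5-fold and 82% of those lowered 1.5-fold. There were 12 calls among unchanged genes, and 5 of 100 unchanged lists stood apart. Those lists were random draws of genes with independent counts, so that share is set by the method. It gives no false rate for lists of related genes. A simulated GC trend over 14617 genes gave the immediate early list a median of -0.26, which was -0.03 (percentile 2.93) after removal of the trends. With that list also lowered 2-fold, it was -0.96 after removal. The simulated trend was straight, with Poisson counts and a rank correlation with GC content of -0.90, against -0.307 in the real libraries. It therefore does not show how well removal works on the real trend. The coefficient of variation estimate returned 0.0998 for a simulated 0.1 and 0.298 for 0.3 over 14656 genes. Alternatives covered other thresholds, scalings (DESeq2 1.42.0 size factors, total counts), pseudocounts, quantifications, left-out libraries and removal of GC and length trends from the list shifts. Removal of those trends from the counts of genes and the spread, GC-matched random lists, a trend on GC-rich windows (100 bases at 65 percent GC or more), a centred quantification ratio, thinning of replicate 1, list medians under total-count scaling, the ratios of the named genes in the second transcript tables, 1000 draws of random gene sets of the lists' sizes for the correlation with GC content and the 31-base words of Gm47283 and Mid1-ps1 were added after the data were seen. Python 3.11.15 with SciPy 1.17.1 was used for all other steps. The BAM and signal files named in the deposited notes were not used here.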

Results

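Poly(A)+ RNA from the left cerebral cortex of adult C57BL/6 mice was sequenced in 2 libraries, replicates 1 and 2 of a single group. The gene tables held 51888490 fragments on genes in replicate 1 and 26776276 in replicate 2. Mean fragment lengths were inferred from the deposited effective lengths of long transcripts, the positions at which a fragment could start. They were 164 and 124 bases by the first transcript tables and 133.9 and 98.3 by the second. With no second group the values describe the tissue and the difference between the libraries. Levels are mean TPM ± SD over n = 2 libraries throughout, and coordinates are on mm10 with GENCODE M21 genes.

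The first question was which genes the cortex expressed most. Cst3 (cystatin C, a secreted protease inhibitor; ENSMUSG00000027447.6, chromosome 2, 148871722 to 148875692) had the highest nuclear protein coding level at 9463 ± 1804 TPM. It was followed by Fth1, the ferritin heavy chain, at 9169 ± 639. Apoe, a lipid carrier made by astrocytes, reached 6578 ± 649.6 (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188), and Ptgds, a prostaglandin D synthase, reached 6519 ± 1376. Also among the 20 highest were Ppia, the respiratory chain genes Cox8a, Cox4i1 and Cox6c, the ATP synthase gene Usmg5, the ribosomal protein genes Rpl41, Rps29, Rpl38 and Rplp1, Ckb, Actb, Calm2 and Ubb, from 6383 ± 170.3 for Ppia down to 3136 ± 966 for Ubb. Several of these genes, among them Ppia and the ribosomal protein genes, have processed pseudogene copies, so their levels are uncertain to the extent that reads were shared. In all, 13800 genes were detected, of which 12448 (90.2%) were protein coding. Mitochondrial genes held 6.77% and 6.78% of fragments in replicates 1 and 2, and mt-Rnr2, a ribosomal RNA, alone held 4.34% and 4.23%.

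Neuronal and glial markers set the cell type levels. Pan-neuronal genes had a median of 380.1 ± 20.3 TPM, led by the synaptic membrane protein Snap25 at 2545 ± 262 and the neuronal enolase Eno2 at 588 ± 227, with the neurofilament gene Nefm lowest at 137 ± 27.8. Oligodendrocyte genes followed at 108 ± 9.83, with the myelin gene Mbp at 2055 ± 8.12 and Ermn lowest at 26.5 ± 6.14. Astrocyte genes stood at 101 ± 12.3, with Aldoc at 1263 ± 189, the glutamate transporter Slc1a2 at 176 ± 15.8 and Slc4a4 at 27.1 ± 11.8. The oligodendrocyte median lay above the astrocyte median in both libraries, 101 against 92.1 in replicate 1 and 115 against 109 in replicate 2, and no test was run. The list medians depend on which marker genes were chosen, so they do not rank cell types by abundance. Excitatory neuron genes had a median of 40.6 ± 7.42, with the kinase Camk2a at 965 ± 166, Arpp21 at 475 ± 172 and Neurod2 at 8.85 ± 2.60. Microglia genes stood at 29.2 ± 4.09, with Tyrobp at 92.4 ± 7.33 and Sall1 at 1.76 ± 0.318. GABAergic interneuron genes had a median of 21.2 ± 1.97, with Lamp5 at 252 ± 38.5, the GABA synthesis enzyme Gad1 at 138 ± 34.2 and Adarb2 at 3.31 ± 0.127. Endothelial genes stood at 13.3 ± 0.799, with the tight junction gene Cldn5 at 113 ± 26.2, Itm2a at 77.7 ± 7.44 and Cdh5 at 1.18 ± 0.509.

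These 7 of the 14 cell type lists had a median of at least 10 TPM. Below them lay oligodendrocyte precursors at 7.88 ± 3.13 (Olig1 47.8 ± 3.95, Sox10 16.3 ± 15.5, Vcan 2.42 ± 0.834) and erythroid genes at 6.94 ± 3.50 (Hba-a2 26.6 ± 17.2, Hbb-bs 18.0 ± 3.61, Slc4a1 0.005 ± 0.00707). The globin genes are close copies of one another, and the split of reads between them is uncertain. Ependymal genes had a median of 5.34 in both libraries, with Rarres2 at 21.7 ± 2.503, Dynlrb2 at 6.80 ± 0.368 and Foxj1 at 1.90 ± 1.52. Fibroblast and meningeal genes stood at 4.43 ± 1.71, where Ptgds far exceeded the collagen-binding Dcn at 16.7 ± 1.74 and Col1a2 at 1.52 ± 0.332. Mural genes had a median of 3.23 ± 0.760 (Vtn 44.0 ± 4.36, Rgs5 13.4 ± 3.44, Myh11 0.35 ± 0.0424). Border macrophage and leukocyte genes stood at 0.547 ± 0.0106, with Pf4 at 11.5 ± 0.163, S100a8 at 1.35 ± 0.382 and Cd3e at 0.045 ± 0.00707. Choroid plexus genes had a median of 0.39 ± 0.0707, although the thyroid hormone carrier Ttr reached 47.1 ± 10.2, with Kcnj13 at 4.42 ± 0.643 and Aqp1 at 0.025 ± 0.00707. The order of the 40 lists was close in the libraries (Spearman rho 0.971 across lists, which share genes and are not replicates).

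**Figure D1:**
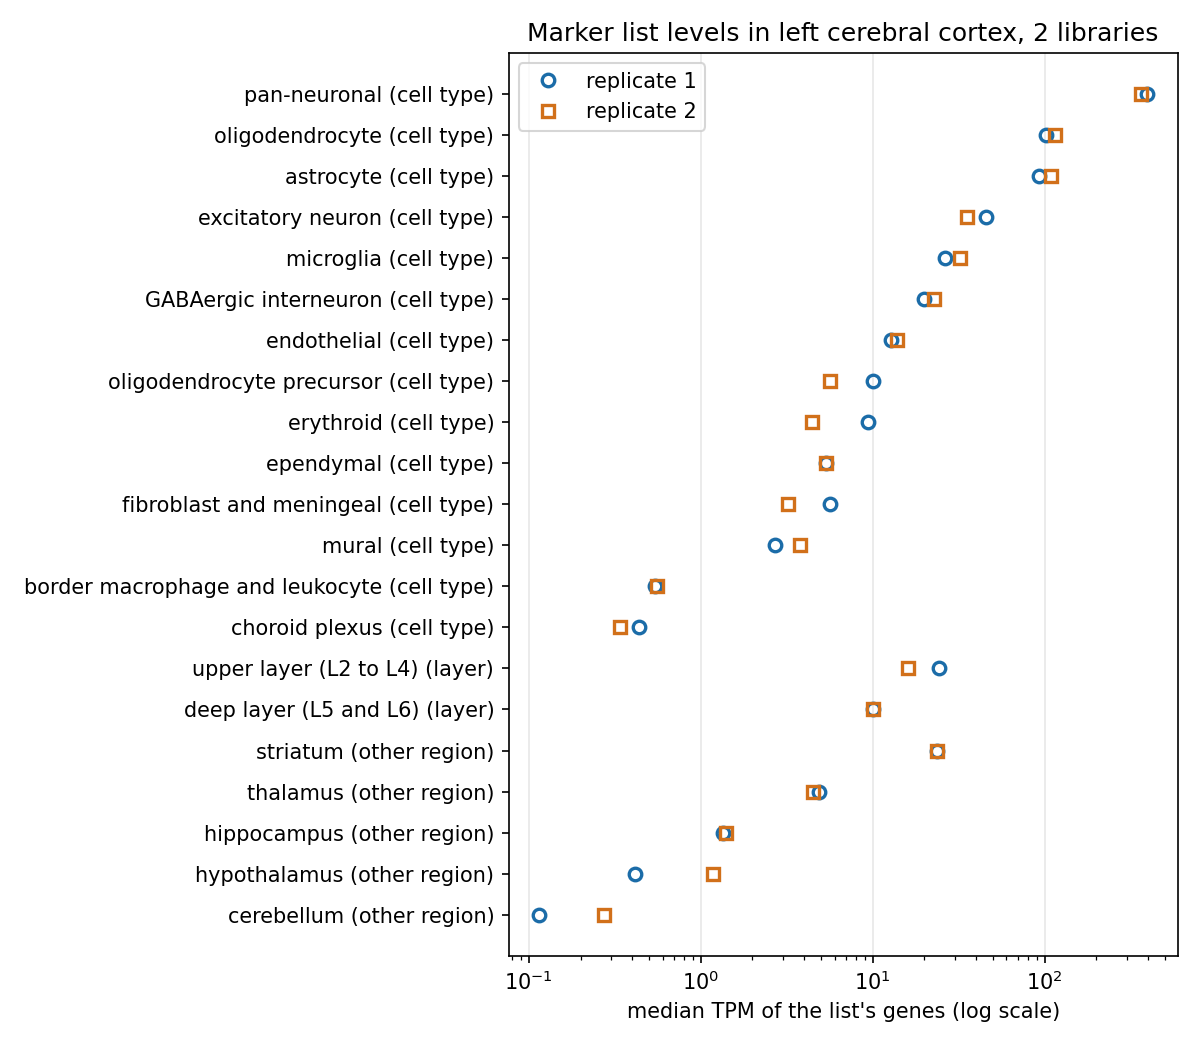
Median TPM of each gene list in replicate 1 and replicate 2, on a log axis, 1 point per library. Pan-neuronal, oligodendrocyte and astrocyte genes led the cell type lists at 380.1, 108 and 101 TPM on average.

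Marker genes of the cortical layers and of other brain regions were measured next. Upper layer genes had a median of 20.1 ± 5.66, with the calcium buffer Calb1 at 120 ± 27.9, Rasgrf2 at 56.4 ± 18.0 and Otof at 1.76 ± 0.177. Deep layer genes stood at 10.04 ± 0.0283, with Pcp4 at 1021 ± 133, Etv1 at 36.1 ± 1.85 and Nxph4 at 1.67 ± 1.20. Striatal genes had a median of 23.6 ± 0.0884, above the deep layer list; Ppp1r1b was at 183 ± 20.1 and the dopamine receptor gene Drd2 at 4.54 ± 0.191. Thalamic genes stood at 4.70 ± 0.244 (Tcf7l2 46.0 ± 1.99, Tnnt1 6.43 ± 0.841, Gbx2 0.07 ± 0.0424) and hippocampal genes at 1.37 ± 0.0460 (Spink8 3.48 ± 2.23, Fibcd1 2.46 ± 0.212, Dsp 0.03 ± 0.0283). Hypothalamic genes had a median of 0.795 ± 0.537 (Pomc 5.21 ± 0.0636, Avp 3.23 ± 3.05, Oxt 0.34 ± 0.113) and cerebellar genes of 0.195 ± 0.113 (Calb2 8.80 ± 5.93, Cbln1 1.25 ± 0.346, Barhl1 0.01 ± 0.0141). Some of these genes, such as Ppp1r1b, Tac1 and Calb2, are also expressed by cortical cells.

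Among the functional lists, mitochondrially encoded protein genes had the highest median at 1917 ± 476 TPM, with mt-Atp8 at 18091 ± 343, mt-Atp6 at 14375 ± 359 and mt-Nd4l at 25.5 ± 36.0. The mt-Nd4l level holds for the gene tables alone, since its counts differed widely between the quantifications. Cytosolic ribosomal protein genes followed at 1238 ± 78.4, with Rpl41 at 5768 ± 258, Rplp1 at 3256 ± 68.9 and Rpl5 at 71.9 ± 17.7. Synaptic vesicle genes stood at 250.1 ± 80.9 (Snap25 first, Rab3a 883 ± 216) and heat shock genes at 78.7 ± 10.7 (Hspa8 2960.4 ± 708, Hsp90aa1 610.2 ± 156, Hspa1b 0.64 ± 0.368, a near copy of Hspa1a). Cholesterol synthesis genes had a median of 37.1 ± 0.863 (Msmo1 158 ± 4.89, Hmgcs1 144 ± 4.65), immediate early genes of 35.3 ± 21.1 (Junb 183 ± 113, Egr1 102 ± 60.6, Fosb 1.75 ± 1.05) and GABA-A receptor subunits of 29.5 ± 0.626 (Gabrd 89.1 ± 4.57, Gabra6 0.02 ± 0.0283). Long noncoding RNAs stood at 28.4 ± 5.83 (Gas5 836 ± 300.5, Malat1 809 ± 102, Miat 1.12 ± 0.389), neuropeptides at 28.1 ± 5.22 (Cck 2080 ± 424, Npy 653 ± 137, Nts 2.62 ± 1.598) and glucocorticoid response genes at 26.2 ± 4.57 (the metallothioneins Mt1 909 ± 14.6 and Mt2 226 ± 41.3, Plin4 0.13 ± 0.141). Genes associated with Alzheimer disease had a median of 23.6 ± 2.31, with Apoe first, App at 417 ± 23.4 and Abca7 at 1.18 ± 0.0919. Circadian clock genes stood at 18.5 ± 0.0389 (Dbp 64.2 ± 55.9, Tef 56.4 ± 39.1, Per2 2.40 ± 0.170) and ionotropic glutamate receptor subunits at 13.3 ± 4.34 (Gria2 137 ± 30.4, Grin2b 106 ± 11.4, Grin2d 0.805 ± 0.686). The lowest medians were those of complement at 4.95 ± 1.33 (C1qb 158 ± 13.2, C1qa 146 ± 14.5, C3 0.275 ± 0.177), RNAs without a poly(A) tail at 4.13 ± 0.643 (Rny3 82.9 ± 62.2, Rny1 68.7 ± 21.6, Terc 0 in both), interferon response at 4.13 ± 0.916 (Ifi27 87.7 ± 3.03, Ifit3 17.0 ± 5.64, Oas1a 0.91 ± 0.0566), reactive glia at 1.20 ± 0.00354 (Vim 30.9 ± 0.863, Spp1 13.7 ± 1.96, Itgax 0.1 ± 0.0141) and proliferation at 0.637 ± 0.209 (Ccnb1 1.73 ± 0.191, Birc5 1.62 ± 0.361, Mki67 0.095 ± 0.0636). Several medians depended on members below 1 TPM, among them that of the Y-linked and Xist list, which was 0.015 with them and 1.65 without. Without those members the medians were 6.43 for border macrophage and leukocyte, 4.42 for choroid plexus, 13.8 for erythroid, 2.35 for hippocampus, 5.03 for cerebellum, 4.22 for hypothalamus, 6.82 for reactive glia, 1.68 for proliferation and 42.7 for RNAs without a poly(A) tail, and 120 for heat shock genes.

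Sex-linked genes were measured in both quantifications, since the labels call the tissue male in the description and give the sex as not collected. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y held 3, 0, 4 and 2 fragments in the gene table of replicate 1 and 0 each in replicate 2, where 0 allows up to 0.112 CPM. Their sum was 9 and 0 fragments in the gene tables and 65.4 and 24.0 in the second transcript tables, of which Kdm5d made up 41.0 and 18.8. Relative to depth these sums were 0.173 CPM in the gene table and 0.859 CPM in the second transcript table of replicate 1. All chromosome Y genes together held more in the second transcript tables, 1569.7 and 684 fragments (20.6 and 14.7 CPM), against 0.482 and 0.0747 CPM in the gene tables. Of these fragments Gm47283 (chromosome Y, 90784738 to 90816464) held 833 and 449 and Mid1-ps1 (90753057 to 90763485) 205 and 64.0, both named after their values were seen and both at 0 in the gene tables. Of their 31-base words 53.2% and 2.55% occur in no other gene's transcript, so their counts are uncertain, and the other chromosome Y genes held 532 and 171 fragments. Xist, the RNA that coats the inactive X chromosome, held 1408 and 485 fragments in the gene tables and 1944 and 936 in the second transcript tables. Its antisense partner Tsix held 568 and 233, and without stated strand use the reads of the overlapping pair cannot be told apart. The X-linked counterparts Ddx3x and Eif2s3x held 2243 and 6276 fragments in replicate 1 and 1686 and 4061 in replicate 2.

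The libraries were then compared with each other to size the spread behind these levels. Among the 12 genes furthest below in replicate 2 were the death-associated kinase gene Dapk3 (ENSMUSG00000034974.13, chromosome 10, 81183005 to 81193197), with 3622 fragments in replicate 1 and 37 in replicate 2 (log2 ratio -5.33, interval -6.30 to -5.32), and the transcription factor genes Cebpb (1369 and 7 fragments) and Jund (7113 and 137 fragments, -4.74, -5.13 to -4.63). Adnp, Bri3, Nrarp, the AMPA receptor partner Cnih2 (19799 and 749 fragments, -3.87, -4.01 to -3.79), Gm10800, Gm26870, Gm13304 and Gm17167 were also among them, from -6.19 for Gm10800 to -3.87 for Cnih2. In replicate 1 Gm10800 held 3869 fragments in the gene table and 16355 in the second transcript table, and Gm26870 798 and 4104. Over the whole library the second table held 1.47 times as many, so the counts of both genes are uncertain. Gm26825 held 1770 and 0 fragments in the gene tables, at least 333-fold lower in replicate 2 against the floor of 3 counts. Furthest above in replicate 2 were Gm20388, with 0 and 534 fragments in the gene tables (at least 316-fold higher against the same floor), Pagr1a (4.44), Gm45062 (2.79), 4930524O07Rik (2.57), Gm15459 (2.53), Gm20458 (2.39), the phosphatase subunit gene Ppp1r16b (6683 and 19243 fragments, 2.35, 2.31 to 2.39), Wdfy1 (2.15), Gm14391 (2.11), Hist3h2ba (1.92), Snurf (1.89) and Rnf146 (1.79). Of the 12 genes in each direction, 9 of the higher and 6 of the lower overlapped another expressed gene, so their counts are uncertain; Gm26825 and Gm15459 overlap each other. By the counts of the second quantification, 12 of the higher and 11 of the lower genes kept their direction outside the counting interval, but Gm26825 turned to 0.38, with 125 and 115 fragments, and Gm20458 and Gm14391 lay at 0.58 and 0.37. There Gm20388 held 48.8 and 763 fragments, a log2 ratio of 3.80, so its bound holds for the gene tables alone, and Pagr1a lay at 2.59 and Gm15459 at 1.13.

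By the exact binomial test, 9125 of 14656 genes (62.3%) differed between the libraries, 3807 higher and 5318 lower in replicate 2, and 3000 of them by at least 1.5-fold (472 higher, 2528 lower). The test compares those libraries, not conditions, and with 1 library on each side the differences have no replicate check. Under total-count scaling the calls were 5725 higher and 4123 lower, with the median log2 ratio of all genes at 0.09 in place of -0.03. The calls of at least 1.5-fold were then 830 higher and 2065 lower, against 682 and 2817 with no filter on low counts and 258 and 2012 at a mean CPM of at least 5. The median absolute log2 ratio was 0.25 and the common biological coefficient of variation 0.321. Across genes, which are not independent replicates, Spearman's rho was 0.947 and Pearson's r of log2(TPM + 1) 0.960.

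Genes of higher GC content had lower ratios of replicate 2 over replicate 1 (Spearman rho -0.307 across 14646 genes). The median log2 ratio was 0.14 in the 498 genes under 40% GC and -1.31 in the 77 genes above 65%. Genes at least 1.5-fold lower in replicate 2 had a median GC content of 54.9%, those higher 47.6% and all tested genes 50.8%. The trend on GC content took up 11.0% of the variance of the log2 ratio. After removal of the trends on GC content and length, 2620 called genes lay at least 1.5-fold apart (602 higher, 2018 lower), of which 2346 were in the earlier set with the same direction.

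**Figure D2:**
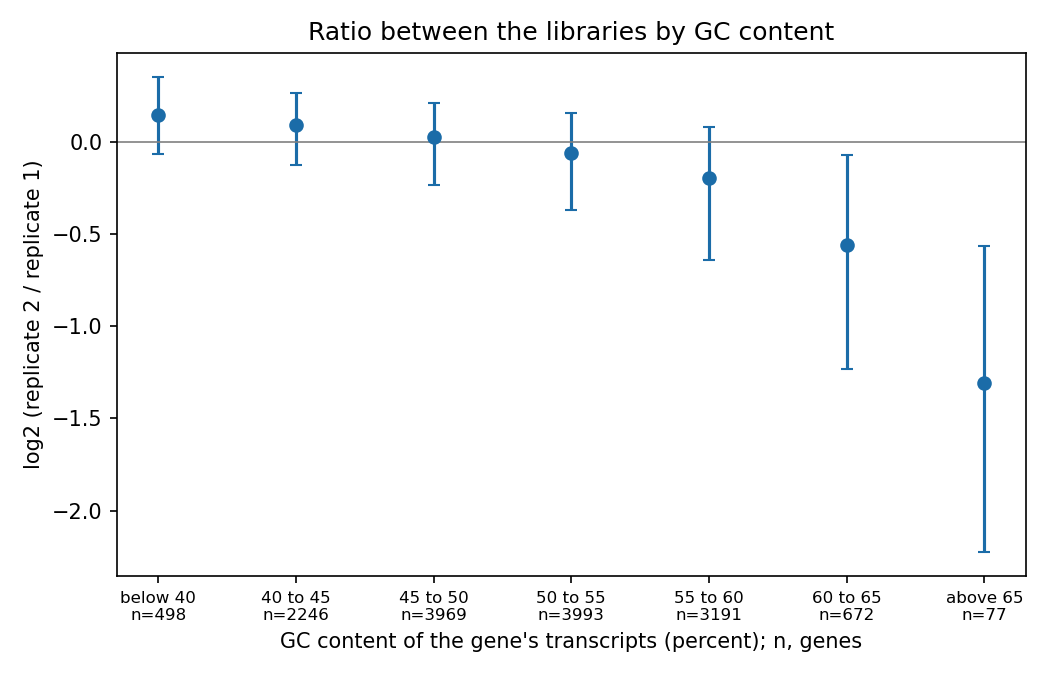
Log2 ratio of replicate 2 over replicate 1 by GC content of the gene, in bins of GC percent, with medians and quartiles. The median ran from 0.14 in genes under 40% GC to -1.31 in genes above 65%.

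The counts of called list members stand beside 62.3% called among all 14656 tested genes (3807 higher and 5318 lower in replicate 2). The test covers counting error only, so such counts alone do not set a list apart. Immediate early genes, transcribed within minutes of neuronal activity, were all lower in replicate 2 (14 of 14 called, 14 adjusted over the list alone). Their median log2 ratio was -1.35, below all 10000 matched random lists, with Egr4 at -3.54 (-3.83 to -3.42; ENSMUSG00000071341.4, chromosome 6, 85511121 to 85513589), Nr4a1 at -1.95, Arc at -1.85 and Ccn1 at -1.67. Synaptic vesicle genes had a median of -0.67 (percentile 0.01), with 12 of 14 lower and 2 higher, the same counts adjusted over the list alone; Syn2 was at -1.78, Syp at -1.62, Vamp2 at -1.47 and Syn1 at -1.27. Circadian clock genes had a median of -0.48 (percentile 0.79), with 10 of 12 lower and 1 higher, the same adjusted over the list alone. The median TPM of that list was 18.485 in replicate 1 and 18.54 in replicate 2, so close list medians can hide differing members. The clock output genes Dbp and Tef were at -2.49 (-2.63 to -2.40) and -1.41, Per1 at -0.94 and Ciart at -0.91, and Arntl, named after its value was seen, was the 1 that was higher at 0.32. Interferon response genes stood at -0.60 (percentile 1.01), with 5 of 9 lower and 0 higher, also adjusted over the list alone, among them Bst2 (-0.89), Irf7 (-0.79), Ifit3 (-0.79) and Usp18 (-0.76). Erythroid genes stood at -0.85 (percentile 1.96), with Hba-a2 (-1.34), Hba-a1 (-1.02), Hbb-bt (-0.69) and Hbb-bs (-0.42) all lower, likewise adjusted over the list alone. Upper layer genes stood at -0.53 (percentile 1.55; 5 lower and 2 higher of 8, the same adjusted over the list alone), with Rspo1 at -1.74, Cux1 at -0.97, Lhx2 at -0.89 and Cux2 at -0.63. Pan-neuronal genes stood at -0.26 (percentile 1.91; 8 lower and 2 higher of 10, the same adjusted over the list alone), with Syp at -1.62, Eno2 at -0.93, Rbfox3 at -0.90 and Nefm at -0.55.

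The other 2 of the 9 lists that stood apart, among 38 placed, lay higher in replicate 2. Neuropeptide genes had a median of 0.26 (percentile 99.85; 8 higher and 1 lower of 12, the same adjusted over the list alone), with Nts at 0.98, Adcyap1 at 0.44, Tac1 at 0.42 and Npy at 0.42. Mitochondrially encoded protein genes had a median of 0.33 (percentile 99.99, 7 higher and 5 lower of 13, the same adjusted over the list alone), with mt-Nd3 at 1.10, mt-Co3 at 0.92 and mt-Nd1 at -0.72. That median was the ratio of mt-Atp8, a gene of 204 bases, whose TPM was 18333.4 in replicate 1 and 17848.5 in replicate 2. By TPM the list's median was 1580 and 2253. The ratios use counts that take no account of gene length against the inferred mean fragment lengths of 164 and 124 bases, an effect that was not tested. In that list mt-Nd4l, which overlaps mt-Nd4, held 285 fragments in replicate 1 and 0 in replicate 2 in the gene tables, at least 53.6-fold lower. It held 18993 and 8173 in the second transcript tables, so that bound and its TPM level hold for the gene tables alone. To which other genes its reads were assigned in the gene tables was not tested. After removal of the GC and length trends the median of the mitochondrially encoded list was -0.21, with the direction reversed, and that of the pan-neuronal list was -0.17, inside the central 95 percent. The medians of immediate early and synaptic vesicle genes after removal were -1.03 and -0.55, both still outside it. The upper layer list lay inside it when random lists were also matched on GC content, and the erythroid list with a pseudocount of 2. All 9 lists kept their direction under total-count scaling.

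**Figure D3:**
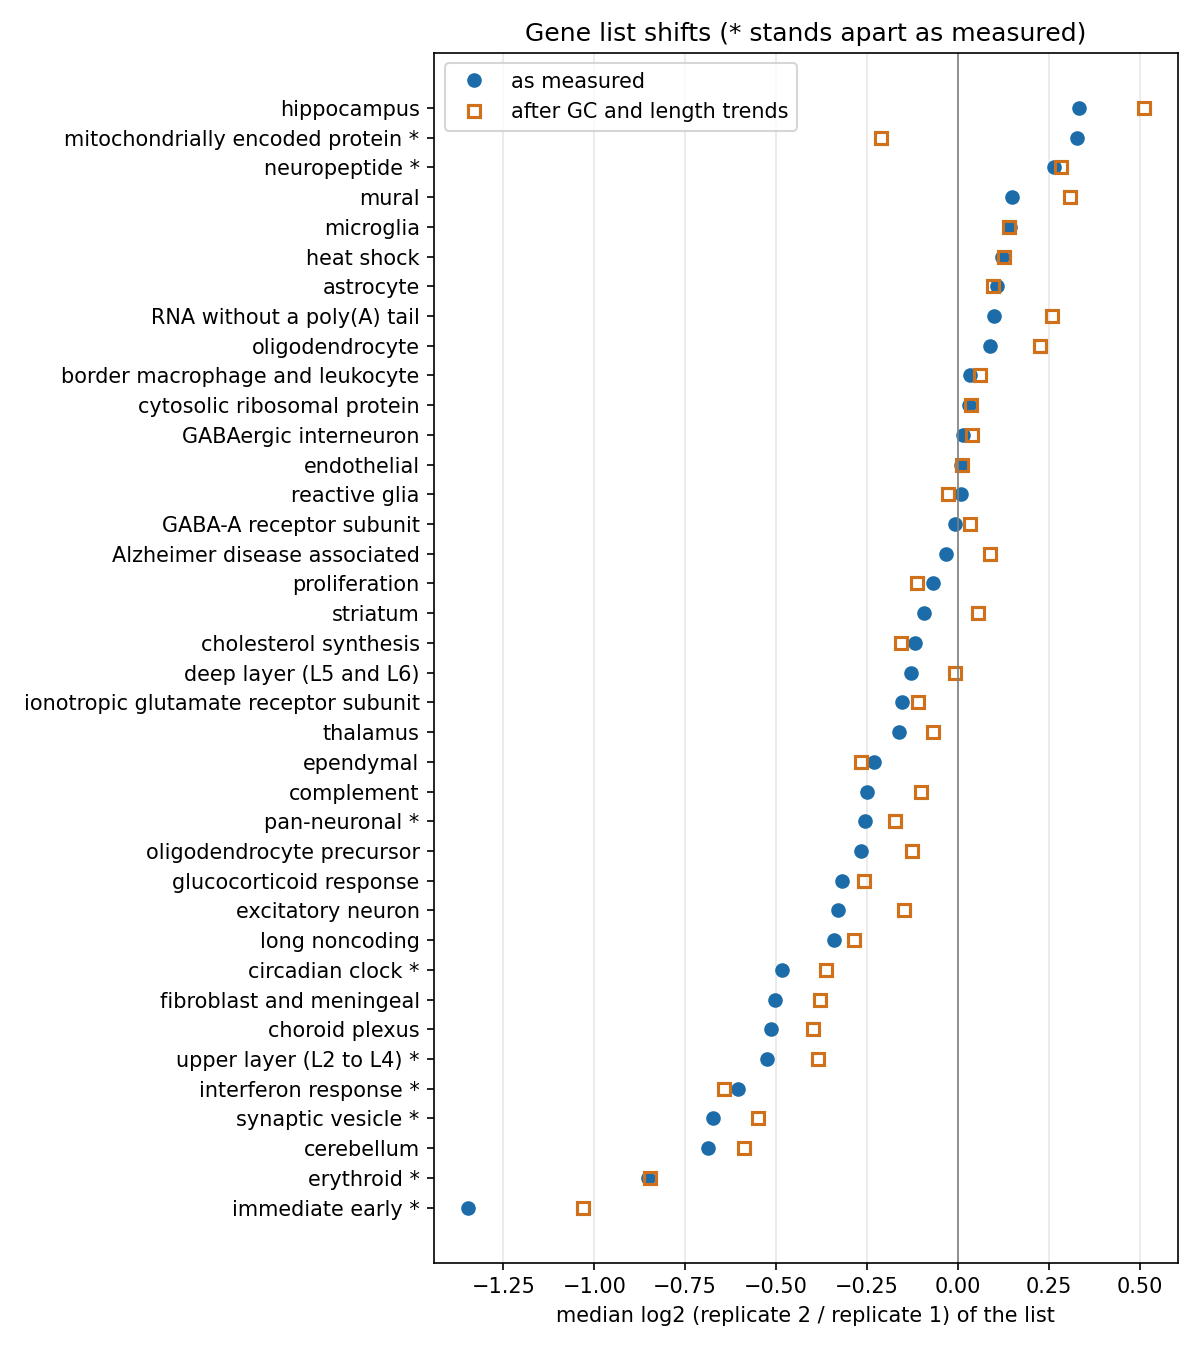
Median log2 ratio of replicate 2 over replicate 1 of each gene list, as measured and after removal of GC and length trends, with a star at lists outside the central 95 percent of random lists as measured. Immediate early genes lay lowest at -1.35, and at -1.03 after removal.

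The remaining 29 lists lay inside the central 95 percent as measured, although 6 of them lay outside it under at least 1 alternative, hippocampal genes under 4. Their medians were -0.69 for cerebellum, -0.51 for choroid plexus, -0.50 for fibroblast and meningeal, -0.34 for long noncoding, -0.33 for excitatory neuron, -0.32 for glucocorticoid response, -0.27 for oligodendrocyte precursor, -0.25 for complement, -0.23 for ependymal, -0.16 for thalamus, -0.15 for ionotropic glutamate receptor subunit, -0.13 for deep layer, -0.12 for cholesterol synthesis, -0.09 for striatum, -0.07 for proliferation and -0.03 for Alzheimer disease associated genes. They were -0.01 for GABA-A receptor subunits, 0.01 for endothelial, reactive glia and GABAergic interneuron genes, 0.03 for cytosolic ribosomal protein and border macrophage genes, 0.09 for oligodendrocyte, 0.10 for RNAs without a poly(A) tail, 0.11 for astrocyte, 0.12 for heat shock, 0.14 for microglia, 0.15 for mural and 0.33 for hippocampus. Under total-count scaling the cholesterol synthesis, striatum, proliferation, Alzheimer disease and GABA-A receptor medians turned to 0.01, 0.03, 0.03, 0.09 and 0.12. By the counts of the second quantification the complement, proliferation, GABA-A receptor, border macrophage and reactive glia medians turned to 0.03, 0.06, 0.01, -0.01 and -0.01. After removal of the GC and length trends those of striatum, Alzheimer disease, GABA-A receptor and reactive glia genes turned to 0.06, 0.09, 0.03 and -0.03. After the GC-rich window trend the same 4 lists turned to 0.06, 0.13, 0.03 and -0.05, and the border macrophage median, like that of GABA-A receptors under DESeq2 size factors, crossed 0 by less than 0.01. In the excitatory neuron list 5 of 10 genes were lower and 3 higher, the same adjusted over the list alone. Named after their values were seen, Tbr1 (-1.69), Nrgn (-1.57), the vesicular glutamate transporter gene Slc17a7 (-1.29), Emx1 (-0.91) and Neurod2 (-0.72) were the lower and Arpp21 (0.29), Sv2b (0.20) and Camk2a (0.09) the higher. Hypothalamic genes (2 tested) and the Y-linked list (1 tested) were too few to place.

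Each library had been quantified in separate ways from the same reads, and the gene table was compared with the second transcript table. Mitochondrial tRNA genes differed most: mt-Th (chromosome M, 11546 to 11612), mt-Tc, mt-Ta, mt-Ts1 and mt-Te were listed at 0 in both gene tables, against 13170 and 18503 TPM for mt-Th and 3956 and 5565 for mt-Te in the second. The miRNA gene Gm24245 was listed at 0 against 11876 and 1124 TPM. In the other direction, the pseudogenes Gm28437 (3615 and 3825 TPM), Gm10222 (1468 and 847), Rpl38-ps2 (690.0 and 627), Gm10221 (156 and 193) and Gm12918 (131 and 93.2) and the miRNA gene Gm22133 (328 and 45.3) were at or near 0 in the second. Of 9895 genes, 280 differed by at least 2-fold the same way in both libraries, 95 higher in the gene table (58 of them pseudogenes) and 185 higher in the second (52 of them pseudogenes, 22 mitochondrial tRNA genes, and 77 genes under 200 bases). With CPM in place of TPM these were 35 and 128, at a mean TPM of at least 1 they were 225 and 672, and at a 1.5-fold limit 175 and 217. Among 9236 protein coding genes 0.509% differed. The median log2 ratio of gene table over second table was 0.39 in replicate 1 and 0.28 in replicate 2, and Spearman's rho across genes was 0.934 and 0.933.

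The main transcript was the same in all 4 transcript tables for 10 of the 15 genes whose isoforms were examined. Snap25-201 held 90.2% and 94.0% of the gene's TPM in the first tables of replicates 1 and 2, App-201 95.9% and 96.0%, Clu-201 92.5% and 93.3%, Gria2-202 88.6% and 88.2% and Mbp-211 74.0% and 77.2%. Pkm-202 held 58.6% and 61.3%, Mapt-205 41.9% and 37.3%, Bdnf-205 41.2% and 40.6% and Camk2g-212 23.7% and 23.3%. Homer1, a postsynaptic scaffold gene, had Homer1-207 at 26.6% in replicate 1 and 0.18% in replicate 2, and Homer1-202 at 26.2% and 61.8%, with 26.8% and 0.605% for Homer1-207 in the second tables. Bin1-201 held 44.98% and 35.9% and Bin1-205 42.5% and 51.6%, and the main transcript also differed among tables for Camk2a and Dlg4. For Dlg4, the gene of a postsynaptic density protein, Dlg4-201 held 70.7% and 43.1% in the first tables but 33.8% and 6.41% in the second. Across 6917 genes the main transcript was the same between libraries for 86.6% (Clopper-Pearson interval 85.8 to 87.4) in the first tables and 86.4% (85.6 to 87.2) in the second. These intervals treat genes as independent and do not cover variation among libraries. Between the tables the main transcript was the same for 89.4% in replicate 1 and 91.9% in replicate 2, and in all 4 tables for 78.4%.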

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

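No test was chosen after the result was seen for the values below, which lie outside the main measurement and above the 3 fragments that a count of 0 allows. The 22 mitochondrial tRNA genes, listed at 0 in the gene tables, held 85911 fragments in the second transcript table of replicate 1 and 55493 in that of replicate 2. Spike-in sequences held 182 and 66 fragments in the second transcript tables and 0 in the gene tables. Rows with numeric names, of unstated identity, held 8.98 fragments in the gene table of replicate 1 and 8.96 in that of replicate 2.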

How the results depend on the processing

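The removal of GC and length trends from gene counts and spread, GC-matched random lists, the GC-rich window trend, the 45 to 55 percent GC subset, the centred quantification ratio, the thinning of replicate 1, total-count scaling of the lists and the second quantification of the named genes were chosen after seeing the data. Detected genes stayed within 1.5 times of the reported count in 8 alternatives, from 9361 at 5 TPM to 16519 at a count of 10, and at 14391 and 14458 with 1 library left out. From 7 to 8 cell type lists reached 10 TPM, the added list being erythroid when members below 1 TPM were left out and oligodendrocyte precursor in replicate 1 alone (10.1 TPM). Of the list levels under the alternatives, 56 moved by more than the spread between the libraries and 183 did not. Leaving out 1 of 2 libraries always moves a mean by less than their SD, so those settings could not count as moved. Leaving out the mitochondrial genes scaled the other lists by the same factor. These counts therefore do not measure how stable the levels are. Leaving out members below 1 TPM changed the order of the lists most (Spearman rho 0.925 with the reported order), as it removes the low members by construction. In the second transcript table the Y-linked and Xist list lay at 0.0710 in place of 0.015 TPM. The 9125 genes differing between the libraries became 3000 when a 1.5-fold difference was also required, since fewer genes meet the added limit. With that limit and the GC and length trends removed they were 2620 (602 higher and 2018 lower, against 472 and 2528). The spread of 0.25 was 0.24 at a mean CPM of 5, 0.26 with a pseudocount of 0.1, 0.21 with a pseudocount of 2, as larger pseudocounts pull ratios toward 0, and 0.23 in genes of 45 to 55 percent GC. From 9 to 10 lists stood apart under each setting, but not always the same: 6 of the 9 did so after the GC-rich window trend, with 4 others. Lists that entered under some setting were hippocampus (4 settings), long noncoding and fibroblast and meningeal (3 each), and mural, excitatory neuron and RNA without a poly(A) tail (1 each). Of the genes named for the largest ratios, Gm26825 alone reversed in the second quantification, to 0.38. The mitochondrially encoded list reversed to -0.21 after GC and length trends were removed, and it lay inside the central 95 percent at 0.22 after the GC-rich window trend. The pan-neuronal list lay inside under 4 settings, the upper layer list under 2 and the erythroid list with a pseudocount of 2; the cause was not tested. The 280 genes differing between quantifications became 897 at 1 TPM and 163 with CPM, and 311 to 343 with 1 library left out. The share of genes with the same main transcript in both tables, 90.7% on average, was 97.9% for transcripts holding at least 60 percent and 93.3% by count; the cause was not tested. No paired analysis was possible because the design has 1 group.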

Other observations

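The tests of the GC pattern and of animals without a Y chromosome were chosen only after the result was seen. Noncoding and pseudogene classes made up part of the detected genes, with 327 processed pseudogenes, 284 lincRNAs and 257 antisense genes. LincRNAs held 2.49% of TPM in replicate 1 and 1.52% in replicate 2, most of it in AY036118 at 16299 and 8435 TPM, which lies within the ribosomal RNA gene CT010467.1 (chromosome 17, 39846353 to 39848827), so that its share of the reads is uncertain.

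Genes of higher GC content had lower ratios of replicate 2 over replicate 1. The rank correlation was -0.303 after replicate 1 was thinned to the depth of replicate 2. Thinning lowers the expected counts of all genes by the same factor, so it cannot decide whether depth played a part. After a trend on gene length was removed the rank correlation was -0.327, so that trend alone does not account for it. The correlation was negative within 29 of the 31 gene lists with enough members (93.5%), but random gene sets of the same sizes gave a median of 80.6% (central 95 percent 64.5 to 93.5), so this share restates the trend. A GC-dependent loss of fragments and other causes linked to GC content could therefore not be told apart, and no biological explanation was tested.

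The immediate early genes were lower in replicate 2, and a GC-dependent loss of fragments or local GC-rich stretches were weighed as technical causes. After removal of the GC and length trends the list's median, -1.03, lay at percentile 0 among 10000 random lists, and after removal of a trend on GC-rich windows, -1.02, also at percentile 0, so neither trend accounts for the whole shift. Library effects other than these trends stay open, and no biological explanation was tested, since the design has 1 group.

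The Y-linked genes lay at or near 0 while Xist did not, against a description of the tissue as male. Assignment of Y-linked reads to copies elsewhere is argued against, as 94.7% of the 31-base words of the Y-linked transcripts occur in no other gene's transcript. The test of animals without a Y chromosome could not decide, since its limits were written after the values were seen and neither was met. The highest sum of Ddx3y, Uty, Kdm5d and Eif2s3y in either quantification was 0.859 CPM, below the 1 CPM that would have excluded such animals. Its 65.4 fragments lay above the 10 under which it was required to stay. All chromosome Y genes together reached 20.6 CPM in the second quantification of replicate 1 and 0.482 CPM in its gene table. Of the 20.6 CPM, Gm47283 and Mid1-ps1, whose counts are uncertain, made up 10.9 and 2.69. In replicate 2, Ddx3y and Eif2s3y held 0 fragments in both quantifications, and Uty and Kdm5d held 5.21 and 18.8 in the second alone. Ddx3x held 1686 and 2941 there. In the gene tables Ddx3y and Eif2s3y held 3 and 2 fragments in replicate 1, against 2243 and 6276 for Ddx3x and Eif2s3x. Xist held 1408 fragments in replicate 1 and 485 in replicate 2. For these genes the values argue against the description of either library as ordinary male tissue. The chromosome Y fragments of the second quantification, given above, lie on the other side. Whether the sex or the sample was mislabelled may not be settled from these tables.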
